A study of Mus musculus with 66 samples.

How the data were processed

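Peak lists of chromatin immunoprecipitation and sequencing from mouse 3T3-L1 adipocytes were analysed for 8 histone marks in 7 conditions: untreated control, Dex at 2 h, 24 h and 6 days, and TNF at the same times. The treatment text names 3T3-L1 cells, as does the cell line label, while the growth text of the labels speaks of cells of the stromal-vascular fraction, and the cell line label was followed. The labels' antibody list names 6 marks. Antibodies for H3K9me3 and H4K20me1 were not given in the sources used here. Samples were grouped by treatment, time and mark as labelled. The 7 whole cell extract samples had no peak list and entered no comparison. The repeats of TNF 2 h for 3 marks were numbered as in the labels and never paired with other samples by number.

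The submitters' processing notes name SAMtools, without a version, and the mouse genome build mm9. The aligner and the peak caller were not given in the sources used here. Each deposited file had 6 columns and no header: chromosome, start, end and 3 values per peak. The fourth column was read as the deposited p-value of each peak, many of them exactly 0. The fifth and sixth columns were read as scores deposited by the authors for each peak, of a scale that no header states. The fifth differed between antibodies at identical intervals and was taken as the score of the immunoprecipitated library. The sixth was equal in 100% of 886 identical intervals between antibodies of one condition and in 1.01% of 8841 between conditions, so it was taken as a value of the whole cell extract of that condition, an inference from the values. All bounds were multiples of 25 bp as deposited, before starts were changed to count from 1. The shortest peak was 500 bp in H3K27ac, H3K4me1, H3K4me3 and H3K9me3 lists and 5000 bp in the others, so shorter enriched stretches are absent by construction. The lists were made per library and not on pooled samples. Longer lists can come from deeper sequencing or stronger enrichment as well as from more marked chromatin, and with no counts these could not be separated by depth. Scores were used only to describe, rank or filter peaks within a list.

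Peaks on the 19 autosomes, X and Y were kept, and those on unplaced contigs left out. Similarity of 2 lists was the Jaccard index of covered bases, checked on 1 pair against bedtools 2.31.1 (0.624 from both). For each mark, peaks of the 7 conditions that overlapped or touched were merged into regions, and a list held a region when it covered at least 1 bp of it. Regions held by the 3 lists of a drug and by no other list (called Dex-only or TNF-only), and regions absent from the 3 lists of a drug and held by the other 4 (Dex-absent or TNF-absent), were counted and ranked among all 35 choices of 3 of the 7 lists. This is an exact permutation test with a smallest p of 0.0286, adjusted by Benjamini-Hochberg over 12 tests (H3K27ac, H3K4me3 and H3K4me1). Where TNF 2 h had 2 repeats, each value is the mean of those computed with each repeat in turn. The 3 times of a drug served as its repeated libraries. Within-drug similarity was tested over the 10 splits of the 6 treated lists, equal-time similarity over 6 pairings, and numbers of control-specific regions by rank among the 7 lists. Length-matched shares weighted all H3K27ac regions to the length distribution of a set, over 24 length bins. Unchanged lists for the time course were simulated 100 times, each region being held at its own rate over the 7 lists scaled to the list's size. Simulated shares used the first other time of the drug, and observed shares the mean over both other times. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting over regions only.

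Tests, alternatives and named regions were fixed before the data were examined, and additions are marked as such in the closing section. The rule named, for H3K27ac, the 10 regions per set with the best worst rank of the score among the lists that hold them. Of these, the report prints the leading ones and summarises the rest. Coordinates are mm9 and count from 1. Gene windows, 11 gene lists and motif searches were planned for the case that an annotation or genome of mm9 was at hand. The annotation in use belonged to another build, so these were not analysed here and no gene was named from a position. Alternatives were overlap of at least 50% of a region, merging within 500 bp, 1 kb bins, lists of equal length (the strongest peaks by score, as many as in the shortest list: 50474 for H3K27ac, 104820 for H3K4me1 and 19447 for H3K4me3), autosomes only, other uses of the repeats, and leaving out each time. The region counts were tested on simulated data: 200 regions specific to Dex and as many specific to TNF were added to simulated unchanged H3K27ac lists in each of 20 draws over 82471 regions, and 99.3% of those for Dex were recovered. After adding, the Dex choice was among the top 2 in 20 draws, and in 0 draws without. This checks the counting only. The simulated lists were independent of each other and did not differ in size, unlike the real ones, where 369 Dex-only regions ranked 6. What number of regions the ranking would detect in the real lists was therefore not tested. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.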

Results

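The data described how histone marks were placed along the genome of 3T3-L1 adipocytes, fat cells differentiated from a mouse fibroblast line. Cells were left untreated (control) or were treated with dexamethasone (Dex, a synthetic glucocorticoid, 20 nM) or with tumor necrosis factor-alpha (TNF, an inflammatory cytokine, dose not given in the sources used here). Both agents are used to make adipocytes resistant to insulin, and the stated purpose was to follow chromatin changes at an early (2 h), an intermediate (24 h) and a late (6 days) time. Chromatin immunoprecipitation and sequencing was done for 8 marks: H3K27ac (active promoters and enhancers), H3K4me1 (enhancers), H3K4me3 (promoters), H3K79me2 and H3K36me3 (bodies of transcribed genes), H3K27me3 (Polycomb repression), H3K9me3 (heterochromatin) and H4K20me1. Of 66 samples, 59 came with a peak list. The other 7 were whole cell extract. Each mark had 7 conditions with 1 list each, except that H3K4me1, H3K36me3 and H3K27me3 were profiled with 2 repeats at TNF 2 h. Read depth was unknown, since the files gave peaks and not counts. Nothing in the labels said whether the lists came from separate cultures, so every p-value below measures only the spread between these lists.

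The lists of H3K27ac held 50474 to 61101 peaks and covered 99.1 to 127 Mb, the most in the control. H3K4me1 lists covered 119 to 283 Mb and H3K4me3 lists 37.1 to 62.0 Mb. H3K79me2 varied least, with 345 to 390 Mb, and H3K36me3 lists covered 274 to 386 Mb. H3K27me3 lists ranged from 230 to 549 Mb. H3K9me3 lists ranged from 10.3 to 111 Mb and H4K20me1 lists from 35.5 to 345 Mb. The repeats of TNF 2 h set the scale for such differences. The second H3K4me1 repeat covered 1.61 times as many bases as the first, and the Jaccard index of the repeats (shared bases over bases covered by either) was 0.569, within the range of 0.370 to 0.592 between either repeat and the other H3K4me1 conditions. The repeats had a Jaccard index of 0.810 for H3K36me3 and 0.650 for H3K27me3, above every value with other conditions, of which the highest were 0.783 and 0.578.

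The first comparison asked whether lists of one drug resembled each other across time. For H3K27ac the mean Jaccard index was 0.657 over pairs of one drug and 0.582 over pairs of different drugs. The difference of 0.0751 was the highest of the 10 ways of splitting the 6 treated lists into 3 and 3, of which the next gave 0.0169 (exact permutation test, one-sided, p = 0.1, the smallest this design allows; 0.32 after Benjamini-Hochberg adjustment over 8 marks). H3K27ac lists of Dex 24 h and Dex 6 days were the closest, with 0.736. The Jaccard index of the control H3K27ac list was 0.616 to 0.679 with the Dex lists and 0.566 to 0.640 with the TNF lists. These ranges overlap, and the lowest value was that of TNF 6 days. H3K4me1 also gave its highest difference for the real split (0.0316, exact p = 0.1), but on lists whose repeats differed as much as conditions did. Without the lists of 6 days that difference was 0.00238 for H3K4me1, and 0.0530 for H3K27ac. Without those of 24 h it was 0.0389 for H3K27ac. The difference was 0.0397 for H3K4me3 (exact p = 0.2; 0.00249 without 6 days), 0.0235 for H3K36me3 (exact p = 0.2), 0.0191 for H3K27me3 (exact p = 0.3), 0.00226 for H3K79me2 (exact p = 0.5) and -0.0154 for H3K9me3 (exact p = 0.8). Leaving out 1 of the times turned the sign for H3K36me3, H3K27me3, H3K79me2 and H3K9me3. For H4K20me1 the difference was 0.0680 (exact p = 0.2), but from -0.0443 to 0.233 when a time was left out. Of the 6 treated H4K20me1 lists, 4 resembled H3K79me2 lists more than the control H4K20me1 list. Lists of equal time but different drug were closer than lists of unequal time by 0.0210 for H3K27ac and by 0.0562 for H3K9me3. Each had p = 0.167 in an exact permutation test over 6 pairings, the smallest possible, and 0.533 after adjustment. The H3K9me3 lists overlapped little and held 11331 to 117943 peaks. Their equal-time pairs had a Jaccard index of 0.274 at 2 h, 0.160 at 24 h and 0.0492 at 6 days.

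**Figure D1:**
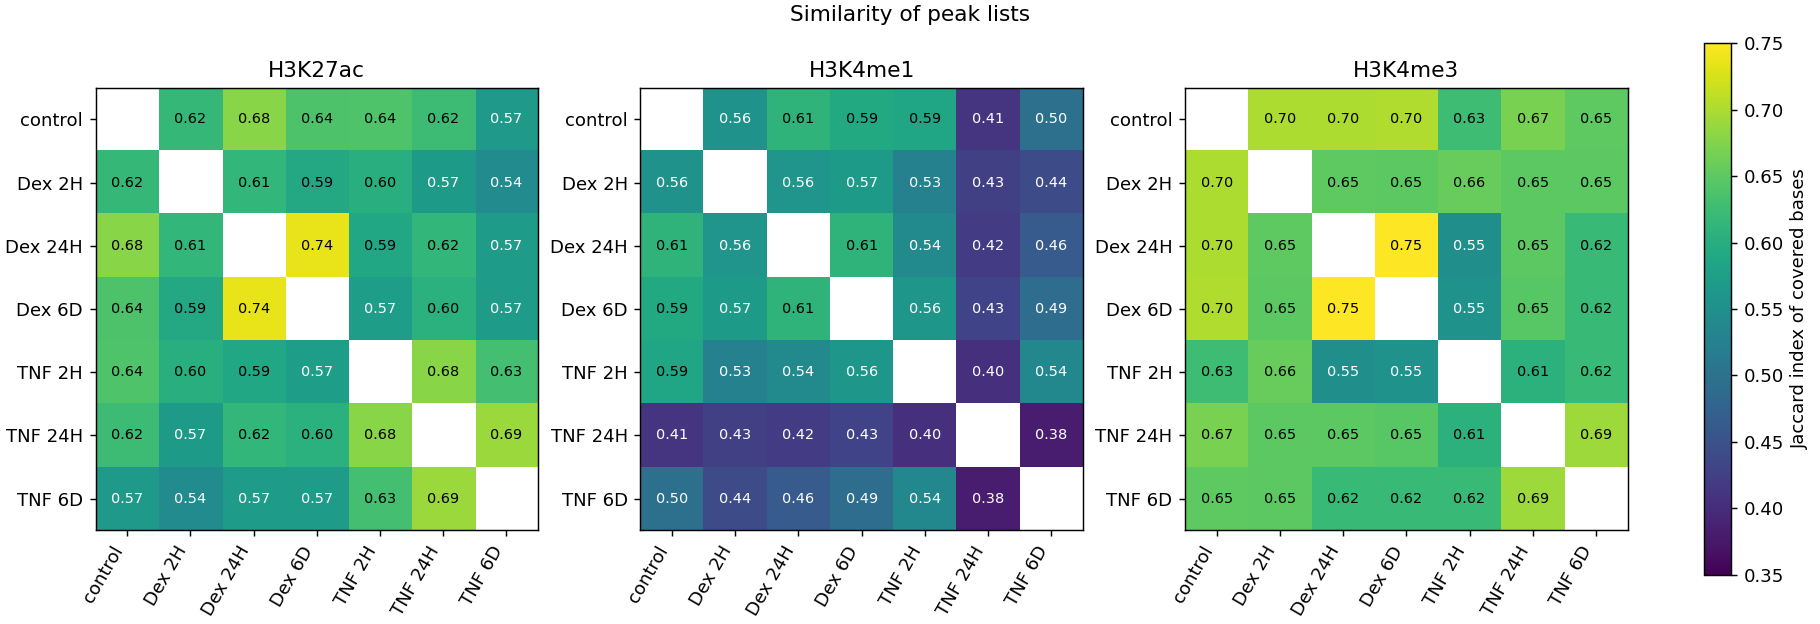
Jaccard index of covered bases (no unit, color and number) for each pair of the 7 conditions of H3K27ac, H3K4me1 and H3K4me3; for H3K4me1 at TNF 2 h the mean over both repeats is drawn. In H3K27ac the pairs within Dex and within TNF average 0.657 and the pairs between drugs 0.582.

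Merging the H3K27ac peaks of all 7 conditions gave 82471 regions, of which 25762 (31.2%) were held by every list. The most frequent pattern that set 3 lists apart was that of TNF: 1986 regions had H3K27ac in all 3 TNF lists and in neither the control nor any Dex list (called TNF-only). That was 20.0 times the median over the other 34 choices of 3 lists and above the highest of them, 1014. Dex-only regions numbered 369, rank 6 of the 35 choices. In the other direction, 791 regions lacked H3K27ac in all 3 Dex lists and had it in the other 4 (Dex-absent), the highest count of 35, and 730 lacked it in all 3 TNF lists only (TNF-absent), the second highest. Exact permutation p-values over the 35 choices (one-sided, smallest possible 0.0286) were 0.0286 for TNF-only, 0.0286 for Dex-absent, 0.0571 for TNF-absent and 0.171 for Dex-only. None of the 12 tests over 3 marks was below 0.05 after Benjamini-Hochberg adjustment, the lowest being 0.137. With all lists set to equal length, Dex-absent regions numbered 522 and ranked second (exact p = 0.0571), TNF-absent regions numbered 778 and ranked first (exact p = 0.0286), and TNF-only regions still ranked first, with 1866. Dex-only regions numbered 546 with lists of equal length (exact permutation p = 0.114). In 1 kb bins the number of TNF-only bins was 3835. Leaving out the TNF 2 h list raised the TNF-only count to 3656, and leaving out the Dex 2 h list raised the Dex-only count to 1447 and the Dex-absent count to 1517. Without the 6 days list of the drug, Dex-absent (1002) and TNF-absent (896) counts were each below that of another choice of lists (1158 and 1039; exact p = 0.133 each).

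**Figure D2:**
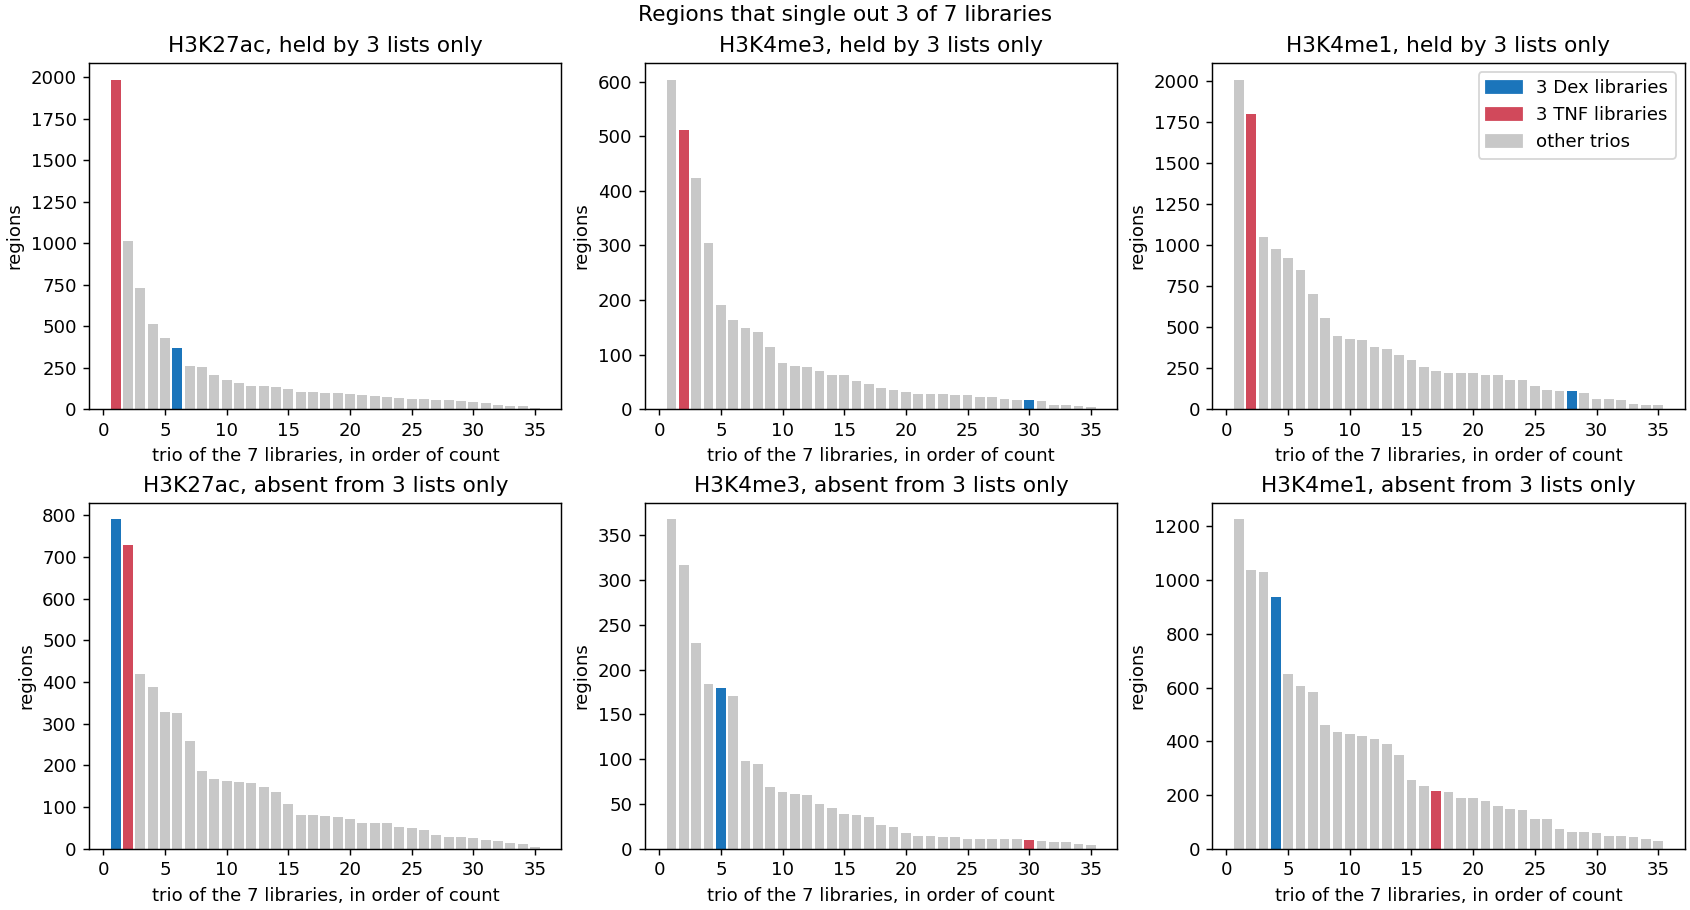
Number of merged regions (vertical axis) held by exactly 3 of the 7 lists (top) or absent from exactly 3 (bottom) for all 35 choices of 3 lists, in order of count (horizontal axis), for H3K27ac, H3K4me3 and H3K4me1. The 3 TNF lists of H3K27ac share 1986 regions, the highest bar of their panel, and the 3 Dex lists together lack 791.

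For each set, the 10 regions with the best rank of the authors' peak score were named. No annotation of the files' genome build was used, so no gene is given, and positions are in mm9. The leading TNF-only regions outside high background were chromosome 16, 49936401 to 49940250 (score 21.6 to 29.2 over the 3 TNF lists), chromosome 10, 48767926 to 48771400 (20.2 to 21.9), chromosome 6, 116327826 to 116332525 (19.7 to 37.5), chromosome 11, 109263526 to 109265775 (19.5 to 24.0) and chromosome 10, 67069251 to 67074150 (19.0 to 31.0). Of the 10 TNF-only regions, 6 had H3K4me1 in the control, 8 had it in all 3 TNF lists (first repeat at 2 h) and 4 had it in no Dex list. H3K4me3 was present in at least 1 TNF list at 9 of them, in a Dex list at 1 and in the control at 0. The region on chromosome 11, 109263526 to 109265775, was among those with no H3K4me1 in the control or with Dex.

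Leading Dex-only regions were chromosome 18, 14359926 to 14362825 (score 18.4 to 24.6 over the 3 Dex lists), chromosome 7, 109504701 to 109507700 (15.9 to 27.9), chromosome 16, 87319126 to 87321925 (11.8 to 15.9) and chromosome 6, 55417901 to 55421400 (11.2 to 13.9). All 10 Dex-only regions had H3K4me1 in the 3 Dex lists, 8 had it in the control and 4 in all 3 TNF lists. The top-ranked Dex-only and TNF-only regions lay in high background. Dex-only chromosome 10, 117105576 to 117108150, scored 159 to 173 with a second score of 65.7 to 77.5, and TNF-only chromosome 11, 3064026 to 3064950, scored 46.9 to 60.8 with a second score of 36.4 to 45.5. That second score did not depend on the antibody, and its median over a whole H3K27ac list was 1.28 to 1.42. Dex-only chromosome 11, 3028451 to 3029675, had second scores of 21.7 to 24.1.

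Dex-absent and TNF-absent regions ranked lower in the lists that held them. The leading Dex-absent regions were chromosome 2, 159970751 to 159973175 (score 8.37 to 17.9 over the 4 lists), chromosome 3, 122645501 to 122648575 (7.57 to 34.0) and chromosome 3, 93586176 to 93588350 (7.50 to 15.8), the only one of the 10 without H3K4me1 in the control. Of the 10, H3K4me1 was present at 9 in the control, at 9 in all 3 TNF lists and at 4 in all 3 Dex lists. The leading TNF-absent regions were chromosome 5, 87164276 to 87165825 (8.31 to 13.1), chromosome 9, 64777426 to 64780500 (6.91 to 9.41) and chromosome 9, 104094626 to 104096700 (6.74 to 9.61). All 10 had H3K4me1 in the control and in every Dex list, and 8 had it in all 3 TNF lists.

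**Figure D3:**
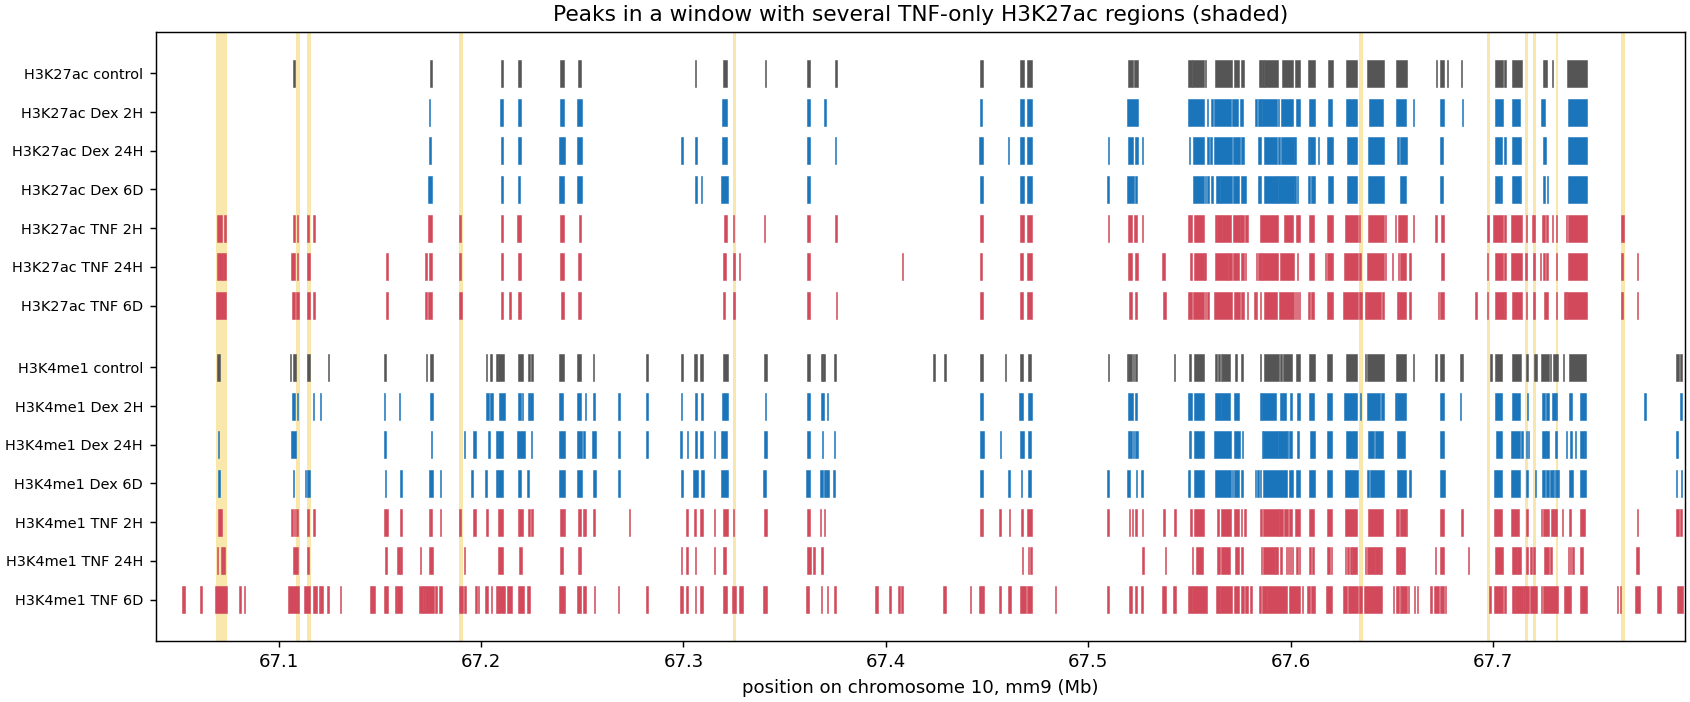
Map of chromosome 10, 67039251 to 67794700 (mm9, horizontal axis in Mb), with the H3K27ac and H3K4me1 peaks of each condition as bars (H3K4me1 at TNF 2 h is the first repeat) and 11 TNF-only H3K27ac regions shaded. The TNF lists hold 61, 62 and 67 H3K27ac peaks in the window, the Dex lists 36 to 44 and the control 43. The window spans one of the densest groups of TNF-only regions, so part of this difference follows from its choice.

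The promoter mark H3K4me3 and the enhancer mark H3K4me1 were counted in the same way. H3K4me3 was held only by the 3 TNF lists at 512 of 49738 regions, 13.8 times the median of the other choices and second of 35 (exact permutation p = 0.0571), while 16 regions were held only by the 3 Dex lists. H3K4me1 was held only by the TNF lists at 1798 regions, the mean over the repeats (1064 with the first and 2531 with the second), also second of 35 (exact p = 0.0571). Dex lists alone held 109 H3K4me1 regions, again a mean over the repeats (172 with the first and 45 with the second). With lists of equal length both TNF counts ranked first, with 197 regions for H3K4me3 and 1079 for H3K4me1 (exact p = 0.0286 each). The Dex-only counts rose to 56 and 302 by that setting. Dex-absent counts were 179 for H3K4me3 (exact p = 0.143) and 939 for H3K4me1 (exact p = 0.114). With lists of equal length they were 63 and 505. Without the Dex 2 h list the H3K4me3 count was 763, above the 213 of the next choice. TNF-absent counts were 10 for H3K4me3 and 215 for H3K4me1, and 55 and 457 with lists of equal length. The 215 is a mean of unlike values, 394 with the first repeat and 35 with the second.

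The other marks were then read at the 4 sets of H3K27ac regions. At TNF-only regions H3K4me1 was present at 48.8% in the control (970 of 1986, 95% exact binomial interval 46.6 to 51.1), at 39.3% ± 1.75 (SD, n = 3 times) with Dex and at 82.1% ± 9.17 (SD, n = 3 times) with TNF. Every TNF list lay above every Dex list (exact permutation test, two-sided, p = 0.1, the smallest 3 against 3 allows; 0.35 after adjustment over 28 comparisons). At Dex-only regions the order was the other way round: 77.0% in the control, 87.8% ± 4.26 (SD, n = 3) with Dex and 71.0% ± 18.1 (SD, n = 3) with TNF (exact p = 0.1), the lowest TNF value being that of 24 h (50.1%). With the first TNF 2 h repeat alone, at 72.9%, the drugs were also separate (exact p = 0.1), but with the second, at 91.3%, they overlapped (exact p = 0.4). At equal list length the shares were 80.8 to 91.1% with Dex and 50.1 to 72.9% with TNF. At Dex-absent regions H3K4me1 was present at 82.7% in the control, 69.9% ± 4.12 (SD, n = 3) with Dex and 90.6% ± 8.05 (SD, n = 3) with TNF (exact p = 0.1). At TNF-absent regions the shares were 92.6%, 91.2% ± 2.23 and 82.2% ± 14.4 (SD, n = 3 each; exact p = 0.4). Over length-matched regions every Dex list lay above every TNF list there, with TNF minus Dex at -12.6 percentage points (exact p = 0.1). At equal list length the difference in shares was -14.7 in place of -8.95.

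At 2 of the sets every TNF list of H3K4me3 lay above every Dex list. At Dex-absent regions it was present at 5.31% in the control, 3.58% ± 2.38 (SD, n = 3) with Dex and 21.4% ± 4.50 (SD, n = 3) with TNF. At TNF-only regions the shares were 2.82%, 2.50% ± 1.16 and 15.9% ± 4.16 (SD, n = 3 each). Both differences had an exact permutation p of 0.1. Over length-matched regions the gap between TNF and Dex at TNF-only regions was 7.44 percentage points (exact p = 0.3). At Dex-only and TNF-absent regions the H3K4me3 shares of the drugs overlapped (exact p = 0.4 and 0.9), although at Dex-only regions Dex was higher at each of the 3 times. Over length-matched regions they did not, and Dex lay above TNF at both: TNF minus Dex was -9.56 percentage points at Dex-only and -6.05 at TNF-absent regions (exact p = 0.1 each). With lists of equal length the gap between TNF and Dex in the shares themselves was 8.43 percentage points in place of 17.9 at Dex-absent regions and 6.28 in place of 13.4 at TNF-only regions. The gene body mark H3K79me2 was present at 39.1% of TNF-only regions in the control, 37.0% ± 0.378 (SD, n = 3) with Dex and 37.2% ± 0.328 (SD, n = 3) with TNF. H3K36me3 was higher in every TNF than in every Dex list at TNF-only (means 35.2 and 28.9%) and Dex-absent regions (26.7 and 20.9%, exact permutation p = 0.1 each). Over length-matched regions these differences had exact permutation p of 0.5 and 0.9. Of the 28 comparisons of marks and sets, 8 reached an exact permutation p of 0.1 in the shares and 14 over length-matched regions. The repressive mark H3K27me3 covered 8.66% of TNF-only regions in the control and 8.54% ± 1.92 (SD, n = 3) with TNF. The Dex share for H3K27me3 was spread from 4.88% to 20.3%, the highest at 6 days. Many H3K27ac regions lay outside H3K4me3: 75.6% of Dex-only, 58.2% of Dex-absent, 67.5% of TNF-only and 70.7% of TNF-absent regions had no H3K4me3 in any list, against 58.1% of all H3K27ac regions. Among regions held by all 7 H3K27ac lists, which were longer (median 3250 bp, against 1600 to 1750 bp in the 4 sets), the share was 14.8%.

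**Figure D4:**
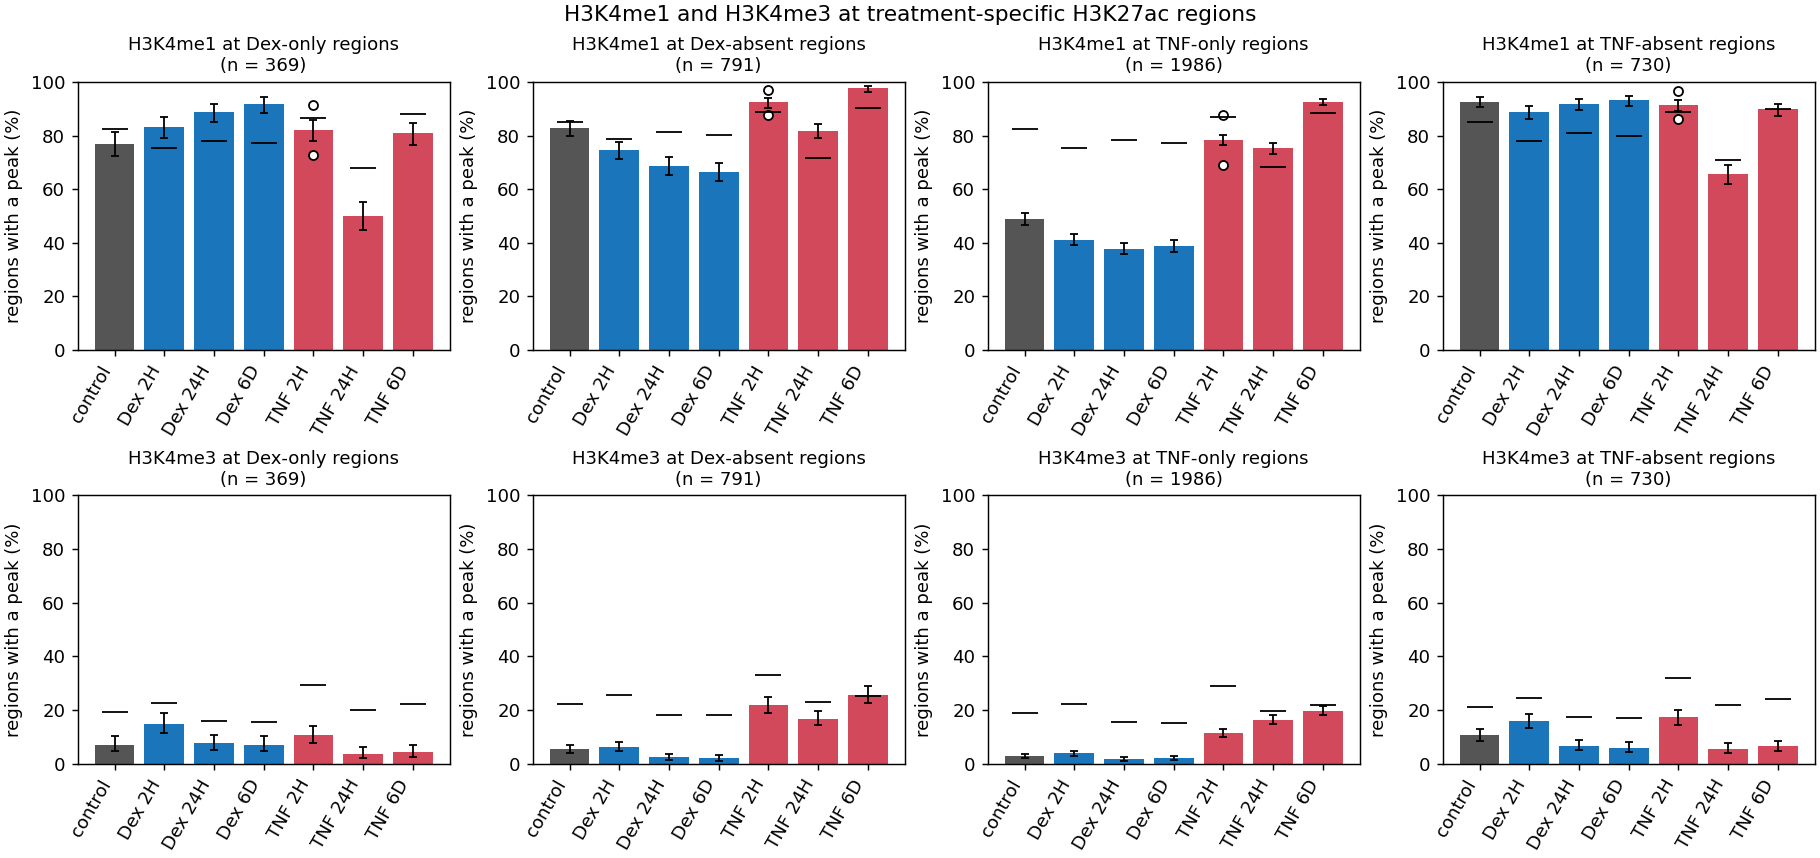
Share of H3K27ac regions of each set (vertical axis, %) with an H3K4me1 peak (top) or an H3K4me3 peak (bottom) in each condition (horizontal axis). Error bars are 95% exact binomial intervals over regions, horizontal ticks the share at length-matched H3K27ac regions, and open circles the repeats of H3K4me1 at TNF 2 h, whose mean is the bar. H3K4me1 at TNF-only regions is 37.9 to 41.2% with Dex and 75.2 to 92.5% with TNF.

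Whether regions with H3K27ac under one drug already carried H3K4me1 in the control was asked next. Control H3K4me1 was present at 48.8% of TNF-only regions, against 82.6% of H3K27ac regions of the same length. At Dex-only regions the share was 77.0% (95% exact binomial interval 72.3 to 81.2) against 82.4%. The comparison regions included those with H3K27ac in the control. Set against length-matched regions that lacked H3K27ac in the control and had it in 3 treated lists of both drugs, TNF-only regions stayed lower (72.5% in the comparison). For Dex-only regions that comparison gave 72.2%, just below the interval, but where H3K4me1 had to cover at least 50% of a region the order turned (56.1% of Dex-only regions against 58.9%). The intervals describe these libraries only.

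The regions of each time were then compared with the control and with the other times. At 2 h, 24 h and 6 days of TNF, 8549, 10374 and 9980 regions had H3K27ac and lacked it in the control, and 42.0 to 43.6% of them, on average, were also held at each of the other TNF times. The Dex lists held 11.8 to 12.8% of the same regions. For Dex the numbers were 5952, 7761 and 5280, with 21.9 to 33.5% held at each other Dex time and 17.9 to 20.2% in the TNF lists. For both drugs the highest share was that of regions of 6 days held at 24 h, with 48.5% for Dex and 49.6% for TNF. These comparisons share 1 control list. In simulations of unchanged lists against that control, 35.1 to 35.7% were held again for TNF and 31.8 to 35.6% for Dex. The simulated rates pooled the lists of both drugs and the control, so they cannot set the drugs apart. Among all regions vacant in the control, each of which had to be held by at least 1 treated list, 31.4 to 34.5% were held by the other TNF lists and 19.0 to 23.2% by the other Dex lists. Lists of single times are not replicated and were not tested. Regions with H3K27ac in the control and none in a treated list numbered 12866 to 16899 for Dex and 14061 to 18684 for TNF. Of these, 62.1 to 79.4% for Dex and 66.0 to 78.8% for TNF were on average also vacant at each of the other times of the drug. In the simulations 49.6 to 64.6% and 53.3 to 61.1% were. These values decide nothing, because simulated short lists also lost regions that every real list held, and only 1 other time was drawn. The lists of the other drug lacked 63.9 to 68.9% of the regions lost with Dex and 59.1 to 65.2% of those lost with TNF. The lists of the same drug lacked more than those of the other at all times except 2 h of Dex (62.1% against 65.1%). The control list was the longest.

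Regions common to both drugs were sought by comparing the control with all 6 treated lists. Only 122 H3K27ac regions were vacant in the control and held by all 6 treated lists, the lowest such number among the 7 lists (218 to 1622 for each treated list in the place of the control; exact p = 1). The control alone held 4832 regions, the highest of the 7 (exact p = 0.143, the smallest possible), but with lists of equal length that number was 2758 and ranked 4 of 7. For H3K4me3, 136 regions were vacant only in the control and 1751 held only there (exact p = 0.714 for each). For H3K4me1 the numbers were 481 (exact p = 0.857) and 4685 (exact p = 0.571).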

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

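The tests of the second score at TNF-only regions and of H3K4me3 at Dex-absent regions were set down before their results were seen, and the other tests in this part afterwards. The comparison with regions held by the control and all TNF lists was added once the first such comparison was found to decide nothing. The search for opposite movement covered 24 list measures and 28 shares.

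One share moved in opposite directions from the control with each drug. H3K4me1 at TNF-only H3K27ac regions was 48.8% in the control, 37.9 to 41.2% in the 3 Dex lists and 69.2 to 92.5% in the TNF lists, repeats included, with drug means 42.8 percentage points apart. The difference between the drugs had an exact permutation p of 0.1, the smallest possible. Part of the lower Dex share came with the Dex lists as a whole: over length-matched regions the excess was -33.8 percentage points in the control and -34.3, -40.3 and -38.5 with Dex at 2 h, 24 h and 6 days. With lists of equal length, 3 further shares of H3K4me1 or H3K4me3 lay on opposite sides of the control. H3K4me1 at Dex-absent regions was 78.1% in the control, 64.6 to 72.9% with Dex and 81.8 to 93.9% with TNF. H3K4me3 was 4.88%, 6.23 to 7.05% and 3.25 to 4.07% at Dex-only regions, and 5.89%, 6.03 to 7.53% and 4.38 to 4.79% at TNF-absent regions. These H3K4me3 shares are low, in sets of 369 and 730 regions, so few regions set the lists apart from the control. No intervals were computed for them, and counting error alone could give such differences.

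The 1986 TNF-only H3K27ac regions could come from longer TNF lists. The TNF lists held 54083 to 58765 peaks, though, fewer than the 61101 of the control, and the Dex lists 50474 to 58085. With lists of equal length the count was 1866, above the 851 of the next choice of 3 lists. The second score, taken as whole cell extract signal, was not raised within the TNF lists. Its median over TNF peaks there was at most 1.05 times the median of the list. Extract of Dex and control samples was not set beside it, as their H3K27ac lists have no peak there. Peaks of other marks carry such a score for part of these regions, as control H3K4me1 does at 970 of them. Those scores were not compared. The H3K27ac immunoprecipitations alone do not account for the set as a whole. The H3K4me1 share over length-matched regions, from another antibody, was higher with TNF than with Dex by at least 26.0 percentage points. That held in all 9 pairs of conditions, with the repeats of TNF 2 h averaged. Such a share cannot speak for single regions. Cultures or chromatin shared by the TNF samples cannot be told apart from the drug, as 0 samples carry a label for batch or date. An effect of TNF therefore stays a hypothesis beside that one and beside extract signal that differs between conditions.

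H4K20me1 lists of Dex 2 h, TNF 2 h, TNF 24 h and TNF 6 days resembled H3K79me2 lists (Jaccard index 0.590 to 0.723) more than the control H4K20me1 list (0.308 to 0.361). A swap with H3K79me2 libraries would leave a partner out of place, but the lowest Jaccard index between H3K79me2 lists was 0.756. Deposition of one library under both names is argued against by the intervals, of which at most 0.0280% were identical. Signal from H3K79me2 in these libraries may be a candidate explanation. Chromosome X held at most 2.23% of their covered bases, near the 2.30 to 2.60% of H3K79me2 lists and away from the 5.64% of the control H4K20me1 list. The 4 lists were picked for their overlap with H3K79me2 lists, from which a similar share largely follows, so it is no separate support. A low share is not particular to such signal, as the Dex 6 days list had 1.34% with a Jaccard index of 0.0857 to 0.0969 to H3K79me2 lists. The Dex 24 h list (6.32%) looked like the control. The 4 lists also resembled each other (0.670 to 0.806), and a real change of H4K20me1 was not tested apart from this.

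H3K4me3 at Dex-absent H3K27ac regions was 21.4% with TNF and 5.31% in the control. Longer TNF H3K4me3 lists could add to this, yet with lists of equal length the lowest TNF share was 7.08%, above the upper bound of 4.18% of the control's exact 95% interval. Whether H3K4me3 was higher with TNF at all partly held regions stays open. At length-matched regions held by 4 lists the TNF excess over the control was 0.195 times that at Dex-absent regions, but 0% of those regions had H3K27ac in the control and all 3 TNF lists, so the choice of regions could set this value. At length-matched regions that did, with 1 or 2 Dex lists besides, the excess was 0.931 times that at Dex-absent regions at 2 h of TNF and 0.394 and 0.395 times at 24 h and 6 days, which decides nothing. Shared chromatin of the TNF samples and an effect of TNF on these regions stay open too.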

How the results depend on the processing

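The filter on the second score, the comparison with mixed regions, single repeats and equal-length lists of other marks at H3K27ac regions, and equal lists of the other 5 marks were chosen after seeing the data. Gene windows, gene lists and motif backgrounds were not run, for want of an mm9 annotation. No paired analysis was possible by replicate number, because the conditions compared share fewer than 2 of these numbers. Dex and TNF lists of equal time can be paired instead, an alternative added later for the shares at H3K27ac regions. TNF was higher in all 3 pairs in 12 of 28 comparisons and Dex in 2, at an exact sign-flip p of 0.25, the smallest that 3 pairs allow. Over length-matched regions this turned to 8 for TNF and 10 for Dex. The 12 include H4K20me1 at every set, a mark whose TNF lists resembled H3K79me2 lists. Over length-matched regions TNF was higher in all 3 pairs of H4K20me1 at no set. Depth is unknown, so list length was evened out by score alone. Causes of the shifts below were not tested, except that a bin is a smaller unit than a region and that leaving out a list loosens the pattern.

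Of 136 region counts under alternatives, 64 stayed within 1.5 times the main count. For H3K27ac, half-region overlap (at least 50%), 500 bp merging, autosomes and the filter on the second score moved none of the 4 counts beyond that. With 1 kb bins the counts were 1027 (Dex-only), 1950 (Dex-absent), 3835 (TNF-only) and 1848 (TNF-absent). Equal lists moved Dex-absent to 522, below the 778 of TNF-absent. Leaving out each time gave 502 to 1447 Dex-only, 1002 to 1517 Dex-absent, 2458 to 3656 TNF-only and 896 to 1464 TNF-absent regions. Single times of Dex were compared with the control, whatever the other lists held. Regions held at that time and not in the control numbered 5952, 7761 and 5280, and the reverse 16018, 12866 and 16899. For TNF these were 8549, 10374 and 9980, and 14061, 15252 and 18684.

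For H3K4me3, in the order Dex-only, Dex-absent, TNF-only and TNF-absent, bins gave 39, 421, 1310 and 23, and equal lists 56, 63, 197 and 55. Leaving out each time gave 50 to 128, 234 to 763, 1129 to 1450 and 16 to 168. For H3K4me1 in that order, bins gave 445, 1936, 3804 and 953, and equal lists 302, 505, 1079 and 457. Half-region overlap gave 178 Dex-only and 373 TNF-absent regions. The union of the repeats gave 39 Dex-only and 28 TNF-absent regions, and their intersection 179 Dex-only, 928 TNF-only and 412 TNF-absent. Leaving out each repeat or time gave 45 to 489, 675 to 1838, 1064 to 7381 and 35 to 1623.

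Regions vacant only in the control numbered 354 (bins) and 214 (equal lists) for H3K27ac, 276 (bins) and 85 (half-region overlap) for H3K4me3, and 1533 and 290 for H3K4me1 by the same settings. Those held only in the control numbered 9386 (bins) and 2758 (equal lists) for H3K27ac and 9498 (bins) for H3K4me1.

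The similarity difference between and within drugs kept its sign in 54 of 60 alternatives, all of those for H3K27ac, H3K4me1 and H3K4me3 included, but not its size. Without 6 days it was 0.00238 for H3K4me1 and 0.00249 for H3K4me3, and leaving out a time gave 0.0389 to 0.123 for H3K27ac. It turned to -0.00706 for H3K79me2 without 6 days, -0.00470 for H3K36me3 without 24 h, -0.0183 and -0.00287 for H3K27me3 without 2 h and 24 h, 0.00145 for H3K9me3 without 2 h and -0.0443 for H4K20me1 without 24 h. The difference by time turned to -0.00204 for H3K4me1 with the union of repeats, ranged from -0.00182 to 0.00665 with single repeats, and was 0.000597 for H3K27me3 with their intersection.

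The control H3K4me1 share minus its comparison was -5.44 percentage points at Dex-only regions, -17.8 with half-region overlap and 4.81 against mixed regions. At Dex-absent regions it was -8.66 and -7.86 with those settings, and at TNF-only regions -43.6 and -23.7. At TNF-absent regions it was 10.5 among regions without H3K4me3 and 1.83 against mixed regions. The TNF minus Dex difference in H3K4me3 at TNF-absent regions turned to -2.05 with equal lists. The other 7 such differences for H3K4me1 and H3K4me3 kept their sign.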

Other observations

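The test of marks other than H3K27ac, H3K4me3 and H3K4me1 for regions specific to a drug, and the comparison of positions of regions, were added to the plan. The 2 tests of position were set down before their results were seen.

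The repressive mark H3K27me3 gave the clearest count for Dex among the other 5 marks. At 475 of 42081 regions (448 with the first TNF 2 h repeat, 501 with the second) H3K27me3 was missing from all 3 Dex lists and present in the other 4, 13.9 times the median and the highest of the 35 choices, of which the next gave 386 (exact permutation p = 0.0286; 0.381 after adjustment over these 20 tests). The 3 Dex lists held the fewest peaks of this mark (19946, 21617 and 24225, against 24287 to 37617 in the others). By covered bases they were not all short, since Dex 6 days covered 495 Mb and the control 420 Mb. Nor were they alike, with a Jaccard index of 0.327 to 0.472 between Dex lists. The 0.327 of Dex 2 h and Dex 6 days was the lowest between any lists of the mark. With lists of equal length, a setting added later, the count was 143 and still the highest, with 118 for the next choice (exact p = 0.0286). Chromosome X held 0.692 to 1.12% of covered bases in the Dex lists of H3K27me3, 2.34% in the control and 1.19 to 3.92% in the TNF lists. For H3K36me3, 114 regions were missing with Dex only (second of 35, exact p = 0.0571; rank 3 with lists of equal length). H4K20me1 was held only by the TNF lists at 170 regions (second of 35, exact p = 0.0571), among the lists that resembled H3K79me2. With lists of equal length that count was 115 and the highest (60 for the next choice). H3K79me2 regions missing with TNF only, 17 and rank 7, became 56 and the highest by that setting (49 for the next; exact p = 0.0286 for both marks, unadjusted).

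A hypothesis was that TNF-only H3K27ac regions lie near each other along the chromosomes. Of the 1986 regions, 23.5% had another within 50 kb, more than in any of 1000 random draws of as many regions held by exactly 3 lists (mean 17.7%, highest 20.7%), a pool that includes the TNF-only regions themselves. The densest window of 1 Mb held 12 of them on chromosome 2, from 102284926 to 102959125, and the next held 11 on chromosome 10, from 67069251 to 67764700. For Dex-only regions the share was 8.40%, within the range of the draws (highest 9.76%) but reached by only 2 of the 1000, against a mean of 3.66%. The bound set beforehand, any value within that range, would have taken even so rare a value as negative, so the result for Dex is left undecided. The densest Dex-only window held 5 regions on chromosome 1, from 155782851 to 155968225. Clustering may reflect shared regulation or the density of enhancers in these windows, which was not separated.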
